A study of Arabidopsis thaliana with 4 samples.

How the data were processed

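Per the labels' protocols, total RNA was taken with Trizol from Arabidopsis thaliana seedlings 2 weeks old, raised on Murashige and Skoog plates in long days of 16 h light at 23 °C and 8 h darkness at 22 °C. Libraries were sequenced as single-end reads of 50 bp, and how RNA was selected for them is not given in the sources used here. There were 4 libraries, 2 from wild type (the Col-0 accession) and 2 from the uba2c mutant. The labels number the libraries of each genotype 1 and 2 and do not say whether they came from separate batches of plants, so p-values measure the spread between these samples, which may be technical.

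Per the submitters' processing notes, FastQC, HISAT2, SAMtools 1.9, featureCounts and edgeR were used with the TAIR10 build; the versions of the other tools, the counting options and the use of strand are not given in the sources used here. The deposited values are a signal per gene, in the form of read counts adjusted to a common library size, and not whole counts; how the authors made this table is not stated. The values behave as the quantile-adjusted pseudo-counts that edgeR makes within each genotype. When the size ratio of each library and 1 dispersion were fitted to the low values, 100% of the deposited values in each library came back to a whole number of reads within a tolerance of 0.001. The recovered libraries held 19720586 (wild type 1), 19723551 (wild type 2), 19847651 (uba2c 1) and 19816174 reads (uba2c 2), and the deposited values summed to 19111252, 19115648, 19098122 and 19438684. The fitted size ratios were 1.03, 1.03, 1.04 and 1.02. All 4 lie above 1, and the common size that the authors adjusted to is not stated. Intervals on reads cover counting error only.

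The design written beforehand assumed counts and named edgeR's quasi-likelihood test, with limma as the test for normalised values. Since the deposited values are normalised, limma 3.58.1 with a mean-variance trend was the main test, run in R 4.3.3 on log2(value + 0.5) for genes with a value of at least 1 in at least 2 libraries. Group was the single term, tests were two-sided, and p-values were adjusted by the Benjamini-Hochberg method at a false discovery rate (FDR) of 0.05. Fold changes are on the log2(value + 0.5) scale, which understates the change of low genes. edgeR 4.0.16 (quasi-likelihood test, TMM) on the recovered reads was added after seeing the data, and called 9138 genes. Of the 32548 genes in the table, 7678 had no read in any library and 22439 were tested. All 32548 identifiers matched a locus of the TAIR10.1 reference annotation, which gave symbols and coordinates. The table holds 0 columns of other samples.

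A set of 28 gene lists with 348 genes was fixed before the data were examined, as were the groups, the main design, most of the alternatives and the rule for named genes. Lists were tested with limma's camera at a preset correlation between genes of 0.01, with adjustment over the 28 lists, and again with an estimated correlation. The rule names UBA2C, the MADS floral repressors, FT, TSF, SOC1 and CO whatever their result. It also names the 10 largest rises and 10 largest falls among genes past the FDR with a mean value of at least 1 and no overlap between the genotypes. From each list that passed its test or had at least 3 members past the FDR it takes up to 4 members by p, and from other flowering-time lists up to 3. It gave 124 genes. Other genes are named in the text as further members of the fixed lists, or are said to have been chosen after their values were seen. Where a group had no read in either library, the fold is a lower bound against a floor of 3 reads per library, and where it had 1 to 3 reads in all and the other group more than 3, the ratio of reads is given with its 95% exact interval. No fold is given where both groups had 3 reads or fewer in all.

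Replicate libraries were compared before they were averaged. Over genes with at least 10 reads in a pair, the squared deviation between libraries had a median of 1.25 times sampling noise for the wild type pair and 1.52 times for the uba2c pair, against 6.58 to 6.80 times between genotypes. The chi-square statistic over its degrees of freedom was 1.49 and 1.97 for the replicate pairs. The replicates therefore differed by more than sampling noise and were kept as separate samples. An excess of this size does not show whether they came from separate plants. The common dispersion from edgeR was equal to a biological coefficient of variation of 2.64%.

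The steps were tested on simulated data in which 200 genes of the uba2c against wild type comparison were changed, 50 at each size. Among 22423 simulated genes tested, limma recovered 30% of the genes changed 1.25-fold, 70% at 1.5-fold, 98% at 2-fold and 100% at 4-fold, and called 0 unchanged genes. edgeR, on 20023 genes, recovered 50%, 84%, 100% and 100%, with 1 unchanged gene called. The changed genes were drawn from those with an expected 50 or more reads per library, so the rates do not cover low genes. Every simulated gene had the common dispersion of these replicates, and fewer genes were changed than were called in the data. The simulation therefore cannot show how many false calls a larger spread between plants would bring.

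Alternatives were other pseudocounts (0.1 and 1), no filter and a stricter filter on low values, edgeR with other size factors and with its likelihood ratio test, DESeq2 1.42.0, limma-voom, a replicate block, leaving out each library, other thresholds, an estimated correlation and limma's fry for lists. Added after seeing the data were edgeR's quasi-likelihood test on recovered reads, edgeR without each library, and a correction for GC content and exon length. Where leaving out a library leaves 1 library in a genotype, that library is assumed to vary like the other genotype's. Among the 124 named genes, 25 overlap another annotated gene and 23 of these overlap one on the opposite strand, so reads of such pairs cannot be told apart without strand. Members of near-identical families (the tandem MAF2 to MAF5 genes, the PDF1.2, CBF and LHCB1 genes) may also share or lose reads. Figures were drawn with matplotlib 3.10.9.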

Results

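RNA was measured by sequencing in 2-week-old Arabidopsis seedlings of the wild type (Col-0, n = 2) and of the uba2c mutant (n = 2), raised in long days. UBA2C is an RNA-binding protein, and the series title links it to ambient temperature, flowering and the transcription of FLOWERING LOCUS M (FLM), which encodes a MADS-domain repressor of flowering. The comparison asks which transcripts differ in seedlings without normal UBA2C function. The libraries held between 19720586 and 19847651 recovered reads. Values are deposited, library-size-adjusted read counts, given as mean ± SD of 2 libraries.

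The UBA2C transcript was lower in both uba2c libraries, at 209 and 234 against 799 and 771 in wild type. Its mean was 785 ± 19.3 in wild type and 221 ± 17.7 in uba2c (n = 2 each), a log2 fold change of −1.83 (SE 0.08, limma adjusted p = 2.64e-06), so the labels were borne out in every library. UBA2C (AT3G15010) lies on chromosome 3 from 5052725 to 5056017 on the plus strand in TAIR10.1, and overlaps AT3G15020 on the same strand. The labels do not say where the gene is disrupted, so the remaining reads cannot be placed against the lesion. Of its relatives in the UBA2 and UBP1 list, UBP1C rose slightly (log2 fold change 0.14), by about the median of the reference genes (0.14). UBA2A, UBA2B, UBP1A and UBP1B did not pass. In that list 1 of 6 genes rose and 1 fell, also when adjusted over the list alone, and the list did not pass as a set (camera adjusted p = 0.381).

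FLM fell with it. FLM (AT1G77080, chromosome 1 from 28955483 to 28960234, plus strand, TAIR10.1) dropped from 610 ± 20.1 to 186 ± 6.73 (n = 2 each), a log2 fold change of −1.71 (SE 0.07, limma adjusted p = 2.94e-06). Its relatives MAF4 and MAF5, MADS-domain repressors encoded in a tandem cluster, fell to 4.86 ± 1.46 from 23.3 ± 5.57 and to 22.3 ± 1.70 from 50.9 ± 0.70 (log2 fold changes −2.16 and −1.17, limma adjusted p = 0.00385 and 0.00406). SVP, a partner of FLM in repressing flowering, was slightly lower (log2 fold change −0.14, limma adjusted p = 0.0281), a call that was lost with DESeq2 (adjusted p = 0.116) and with limma without wild type 2 (adjusted p = 0.173). After a GC and length correction the SVP change shrank to −0.08 (limma adjusted p = 0.154), and edgeR lost it without wild type 2 (0.144), uba2c 1 (0.0649) or uba2c 2 (0.0752), in a range of 0.00701 to 0.191 over all alternatives. MAF2 (log2 fold change −0.19, limma adjusted p = 0.0583), MAF3 (−0.10, adjusted p = 0.420) and FLC (from 4.36 to 1.46, limma adjusted p = 0.120) did not pass. FLC had at most 5 reads in any library, and its ratio of reads, wild type over uba2c, was 3.02 (95% exact interval 0.753 to 17.3). MAF2 did pass with edgeR on recovered reads (adjusted p = 0.0293, with 0.0252 to 0.279 over all alternatives). Of the 7 MADS repressors 4 fell and 0 rose, and 5 fell adjusted over the list alone. The list passed as a set (camera adjusted p = 0.00402, adjusted p = 0.295 with an estimated correlation).

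Other floral repressors were lower too. TEM2, which represses FT, fell from 4097 ± 17.7 to 1795 ± 108 (log2 fold change −1.19, limma adjusted p = 2.03e-06), and TOE1, AP2 and TEM1 changed by −0.72, −0.65 and −0.31. In this list of AP2-type and other repressors 6 of 10 fell and 0 rose, with the same counts adjusted over the list alone (camera adjusted p = 0.00211, adjusted p = 0.282 with an estimated correlation). FT, the mobile flowering signal, rose from 7.27 ± 2.09 to 36.9 ± 9.24 (log2 fold change 2.27, SE 0.34, limma adjusted p = 0.00168), and SOC1, which acts downstream of it, rose from 1059 ± 36.7 to 1367 ± 29.0 (0.37, limma adjusted p = 0.000746). CO (0.22, limma adjusted p = 0.697) and TSF, with at most 2 reads per library, did not pass. CO had 8 and 8 reads in wild type and 8 and 11 in uba2c. Its ratio of reads, uba2c over wild type, was 1.18 (95% exact interval 0.575 to 2.46), so a change within that interval is not excluded. The floral integrators did not move as a set: 3 of 11 rose and 2 fell, or 3 and 3 adjusted over the list alone (camera adjusted p = 0.889), with SPL9 and AGL24 lower at −0.70 and −0.57, and the median of −0.00 differed in sign from the mean of 0.17. The AGL24 call was lost with DESeq2 (adjusted p = 0.0606, with 0.000178 to 0.119 over all alternatives).

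**Figure D1:**
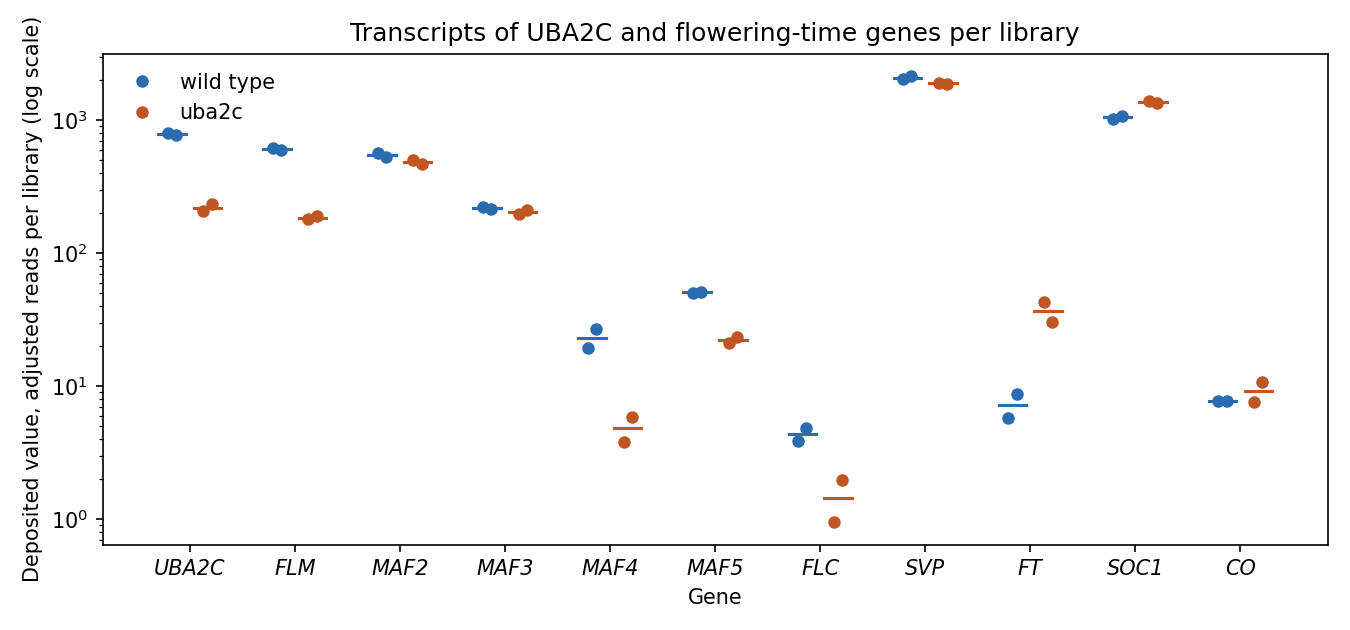
Deposited values (log axis) of UBA2C, the MADS repressors, FT, SOC1 and CO in each wild type library (blue) and uba2c library (orange), with bars at the mean of 2 libraries. UBA2C, FLM, MAF4 and MAF5 lie lower and FT higher in both uba2c libraries, while MAF3 and CO did not pass the test.

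The mutation went with changes in many further genes. The labels give no time of harvest. For any gene here or above that varies over the day, harvest time and genotype cannot be told apart. In limma, 7809 of 22439 tested genes passed an FDR of 0.05 (34.8%), with 3908 higher and 3901 lower in uba2c, and 10140 had an unadjusted p under 0.05. After a GC and length correction the split was 4815 higher and 3625 lower (57.0% higher), and with edgeR on library totals it was 4137 and 4612 (47.3%). Most changes were small: the median absolute log2 change was 0.42, and 513 genes rose and 859 fell at least 2-fold. The first principal component held 66.9% of the variance and separated the genotypes, and the second separated the uba2c libraries from each other. Without uba2c 1 or without uba2c 2, limma called 0 genes, UBA2C and FLM included (7513 and 7412 at an unadjusted p under 0.05), whereas edgeR called 5828 and 6492. Every limma call of a single gene given here shares that limit. DESeq2 called 4804 genes.

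The largest rises included RD29B, which encodes a dehydration-induced protein and went from 37.3 ± 10.4 to 933 ± 62.0 (log2 fold change 4.65, limma adjusted p = 1.72e-06), and FLP1, from 2.91 ± 1.39 to 49.0 ± 2.81. LBD27, a LOB-domain transcription factor gene, had no read in wild type and 13.1 ± 0.51 in uba2c, at least 4.50-fold higher. For AT4G25580, with 1 to 2 reads in each wild type library, the ratio of reads was 27.2 (95% exact interval 8.98 to 135). AT2G44220, AT4G14368, AT4G09110 and AT4G13790 had 1 to 2 reads in all in wild type and ratios of 32.8 (5.49 to 1335), 27.8 (4.60 to 1139), 13.9 (3.51 to 121) and 22.9 (3.71 to 942). AT2G29220 and AT5G04380 had no read in wild type and were at least 4-fold and 2-fold higher. Among the falls, SAG12, a cysteine protease gene used as a marker of late senescence, went from 33.9 ± 8.35 to no read in uba2c, at least 11.7-fold lower. NATA1, an acetyltransferase gene, fell from 186 ± 15.3 to 3.42 ± 3.53 (log2 fold change −5.95, limma adjusted p = 0.000218), PIP5K5, a lipid kinase gene, from 99.3 ± 10.4 to 1.94 ± 1.37, and DPBF2, a bZIP transcription factor gene, from 58.6 ± 13.2 to 1.95 ± 1.42. AT4G13577 fell from 56.2 ± 12.5 to 2.43 ± 0.73. AT4G25707 and AT1G29770 had 2 reads in all in uba2c, with ratios of 22.1 (5.77 to 188) and 20.1 (5.22 to 172), and AT3G17225, AT4G02000 and AT4G19750 had none, at least 5-fold, 3.67-fold and 3-fold lower.

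Genes of the abscisic acid and dehydration response rose together: 13 of 14 were higher and 0 lower, with the same counts adjusted over the list alone (camera adjusted p = 6.27e-10, adjusted p = 0.282 with an estimated correlation). HAI1, a protein phosphatase gene that is also the senescence gene SAG113, went from 71.2 ± 7.66 to 559 ± 37.5, P5CS1 of proline synthesis rose 1.75-fold and RD29A rose 1.83-fold, while LTI30 did not pass. In the list of dark and sugar starvation genes 8 of 11 rose and 1 fell, as also adjusted over the list alone (camera adjusted p = 9.88e-05, adjusted p = 0.295 with an estimated correlation). TPS11 rose 3.42-fold, TPS8 2.14-fold, DIN10 2.11-fold and SEN1 2.04-fold, and DIN2 fell. Heat shock genes showed 7 rises and 1 fall among 17, or 8 and 1 adjusted over the list alone (camera adjusted p = 0.00779, adjusted p = 0.295 with an estimated correlation), with the chaperone gene HSP70-4 up 2.01-fold and HSFA7A up 2.24-fold. In the ambient temperature list 5 of 10 rose and 0 fell, or 6 and 0 adjusted over the list alone (camera adjusted p = 0.000787, adjusted p = 0.282 with an estimated correlation). The members that rose most were the auxin genes IAA29 (163 ± 5.57 to 1320 ± 114), YUC8 (3.06-fold) and IAA19 (2.18-fold), while PIF4 changed by 0.15 on the log2 scale.

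Anthocyanin genes fell: 8 of 12 were lower and 0 higher, or 8 and 1 adjusted over the list alone (camera adjusted p = 0.00209, adjusted p = 0.282 with an estimated correlation). DFR and LDOX, enzymes of the pathway, changed by −2.12 and −1.96 and the regulator PAP1 by −2.54 on the log2 scale, while CHS, earlier in the pathway, was at 0.14 and did not pass over all genes. Of 8 ethylene and jasmonate defence genes 5 fell and 0 rose, also adjusted over the list alone (camera adjusted p = 0.00110, adjusted p = 0.282 with an estimated correlation). Those that fell included the defensin gene PDF1.2C at −3.04 and HEL at −1.13. Hypoxia genes fell in 5 of 10 cases with 0 rises, also adjusted over the list alone (camera adjusted p = 0.00218, adjusted p = 0.282 with an estimated correlation), with SUS4 at −1.51 and ADH1 at −1.26. Among 13 phosphate starvation genes 9 fell and 2 rose, or 9 and 3 adjusted over the list alone (camera adjusted p = 0.00218, adjusted p = 0.282 with an estimated correlation), SPX1 and PHT1;4 at −0.91 and −0.84. Root cell markers went down in 13 of 21 cases and up in 3, also adjusted over the list alone (camera adjusted p = 0.000629, adjusted p = 0.295 with an estimated correlation). The root hair genes PRP3 (−1.93), EXPA7 (−1.89) and LRX1 (−1.47) were among those lower, and the iron transporter gene IRT1 rose from 305 ± 6.23 to 1387 ± 7.93.

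Clock genes were shifted in both directions. Of 11 evening-phased genes 6 fell and 2 rose (camera adjusted p = 0.0227, adjusted p = 0.295 with an estimated correlation), with FKF1 at −1.19, PRR5 at −1.23 and BOA at 1.31. Of 12 morning-phased genes 8 rose and 1 fell (camera adjusted p = 0.0425, adjusted p = 0.295 with an estimated correlation), LHY by 1.37 and CCA1 by 0.27. Cold-response genes fell in 8 of 12 cases and rose in 3 (camera adjusted p = 0.0421, adjusted p = 0.417 with an estimated correlation), with CBF3 at −2.18 and ERD10, which rose, at 0.78. Counts adjusted over the list alone were the same for all 3 lists. Without uba2c 1 or uba2c 2 the camera test on limma's fit passed none of them (adjusted p = 0.137 and 0.0533 for evening, 0.0970 and 0.0749 for morning, 0.111 and 0.0767 for cold), and with edgeR on recovered reads the morning and cold lists were at 0.0645. In all, the morning and cold lists each lost their call in 11 of 22 alternatives and the evening list in 3. With limma-voom the morning list was at 0.0688 and the cold list at 0.173, and the cold list was at 0.375 with DESeq2 and at 0.0557 after a GC and length correction. Over all alternatives the adjusted p ranged from 3.67e-05 to 0.295 for evening, 0.00686 to 0.295 for morning and 0.00348 to 0.667 for cold.

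The remaining lists did not pass as sets in camera on limma's fit, and for several of them the call depended on the test. Salicylic acid genes (4 of 19 up and 7 down, 4 and 8 adjusted over the list alone, camera adjusted p = 0.0563) included WRKY70 at −1.06, and passed as lower without the filter on low values (adjusted p = 0.0486), without wild type 2 (0.0408), after a GC and length correction (0.0486) and with fry (0.0214), in a range of 0.0214 to 0.417 over all alternatives. Light-harvesting and Rubisco genes (5 of 19 up and 11 down, 5 and 12 adjusted over the list alone, camera adjusted p = 0.0674) included LHCA1 at −0.38. They passed as lower with DESeq2 (adjusted p = 0.0122), limma-voom (0.00901) and edgeR on library totals (0.0337), and without uba2c 2 in limma (0.0353) and edgeR (4.28e-05), in a range of 4.28e-05 to 0.721. Within the light-harvesting and Rubisco list, RBCS1A and RCA went the other way from LHCA1. The share of reads rose for RBCS1A from 0.92% and 0.93% in wild type to 1.06% and 1.17% in uba2c. For RCA it rose from 0.47% and 0.48% to 0.54% and 0.57%. Jasmonate and wound genes split, with 7 of 18 up and 7 down, also adjusted over the list alone (camera adjusted p = 0.337): VSP2 was at −1.66, LOX2 at −1.08 and JAZ9 at 1.59. This list passed as lower in 11 of 22 alternatives, among them edgeR on recovered reads (adjusted p = 0.000973), the edgeR fits without each library and DESeq2 (2.00e-05), in a range of 2.00e-05 to 0.564. Leaf senescence genes showed 8 of 16 up and 6 down, or 8 and 7 adjusted over the list alone (camera adjusted p = 0.381), with a median of 0.10 and a mean of −0.13. They passed as higher in 10 of 22 alternatives, among them edgeR on recovered reads (adjusted p = 0.0244), DESeq2 (0.00472) and limma-voom (0.0493), in a range of 0.00472 to 0.613. Iron deficiency genes (2 of 14 up and 4 down, 2 and 5 adjusted over the list alone, camera adjusted p = 0.889) held IRT1, FRO2 at 1.59 and IMA3 at −0.80. Photoperiod genes (4 of 13 up and 5 down, 5 and 5 adjusted over the list alone, camera adjusted p = 0.914, median 0.04 and mean −0.00) included PHYB at 0.88 and SPA1 at −0.69, and glucosinolate genes (2 of 10 up and 5 down, 3 and 5 adjusted over the list alone, camera adjusted p = 0.381) CYP83B1 at −0.63. Floral organ and meristem genes (2 of 11 up and 2 down, also adjusted over the list alone, camera adjusted p = 0.674) had STM at 2.49 and AP3 at −3.02, and the autonomous pathway (1 of 7 up and 1 down, also adjusted over the list alone, camera adjusted p = 0.727) had FLK at 0.28 and FCA at −0.38.

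Polycomb genes (3 of 11 up and 0 down, also adjusted over the list alone, camera adjusted p = 0.0674) had a median of 0.14 and a mean of −0.00. They passed as higher without the filter on low values (adjusted p = 0.0486) and with fry (0.0370), in a range of 0.0370 to 0.417 over all alternatives. VEL1 was at 0.43, and the calls of EMF1 and EMF2 were lost with DESeq2 (adjusted p = 0.0981 and 0.142) and with limma without wild type 2 (adjusted p = 0.0747 and 0.169), and in edgeR without uba2c 1 (0.0811 and 0.0693), in ranges of 0.00171 to 0.169 and 0.00534 to 0.251 over all alternatives. Cell cycle genes (3 of 12 up and 0 down, 2 and 0 adjusted over the list alone, camera adjusted p = 0.114) included KNOLLE at 0.44. Reference genes (4 of 8 up and 0 down, 5 and 0 adjusted over the list alone, camera adjusted p = 0.0674) included SAND at 0.32 and ACT2 at 0.18. Their median was 0.14, so small rises such as those of UBP1C and PIF4 are about the size of the shift in reference genes. With fry, which does not compare a list with other genes, the cell cycle (adjusted p = 0.00686), glucosinolate (0.00686), iron deficiency (0.00831), reference gene (0.00686) and UBA2 and UBP1 lists (0.0175) also passed, and in no other alternative. Of the genes given by the rule and named here, FLC, CO, P5CS1, FKF1, BOA, CBF3, DIN10, ADH1, IMA3, SPL9, EXPA7, KNOLLE and AT1G29770 overlap a gene on the opposite strand. Their values are uncertain where strand was not used in counting. Genes named outside the rule, such as UBP1C, PIF4, CHS and PIL1, were not checked for overlaps.

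**Figure D2:**
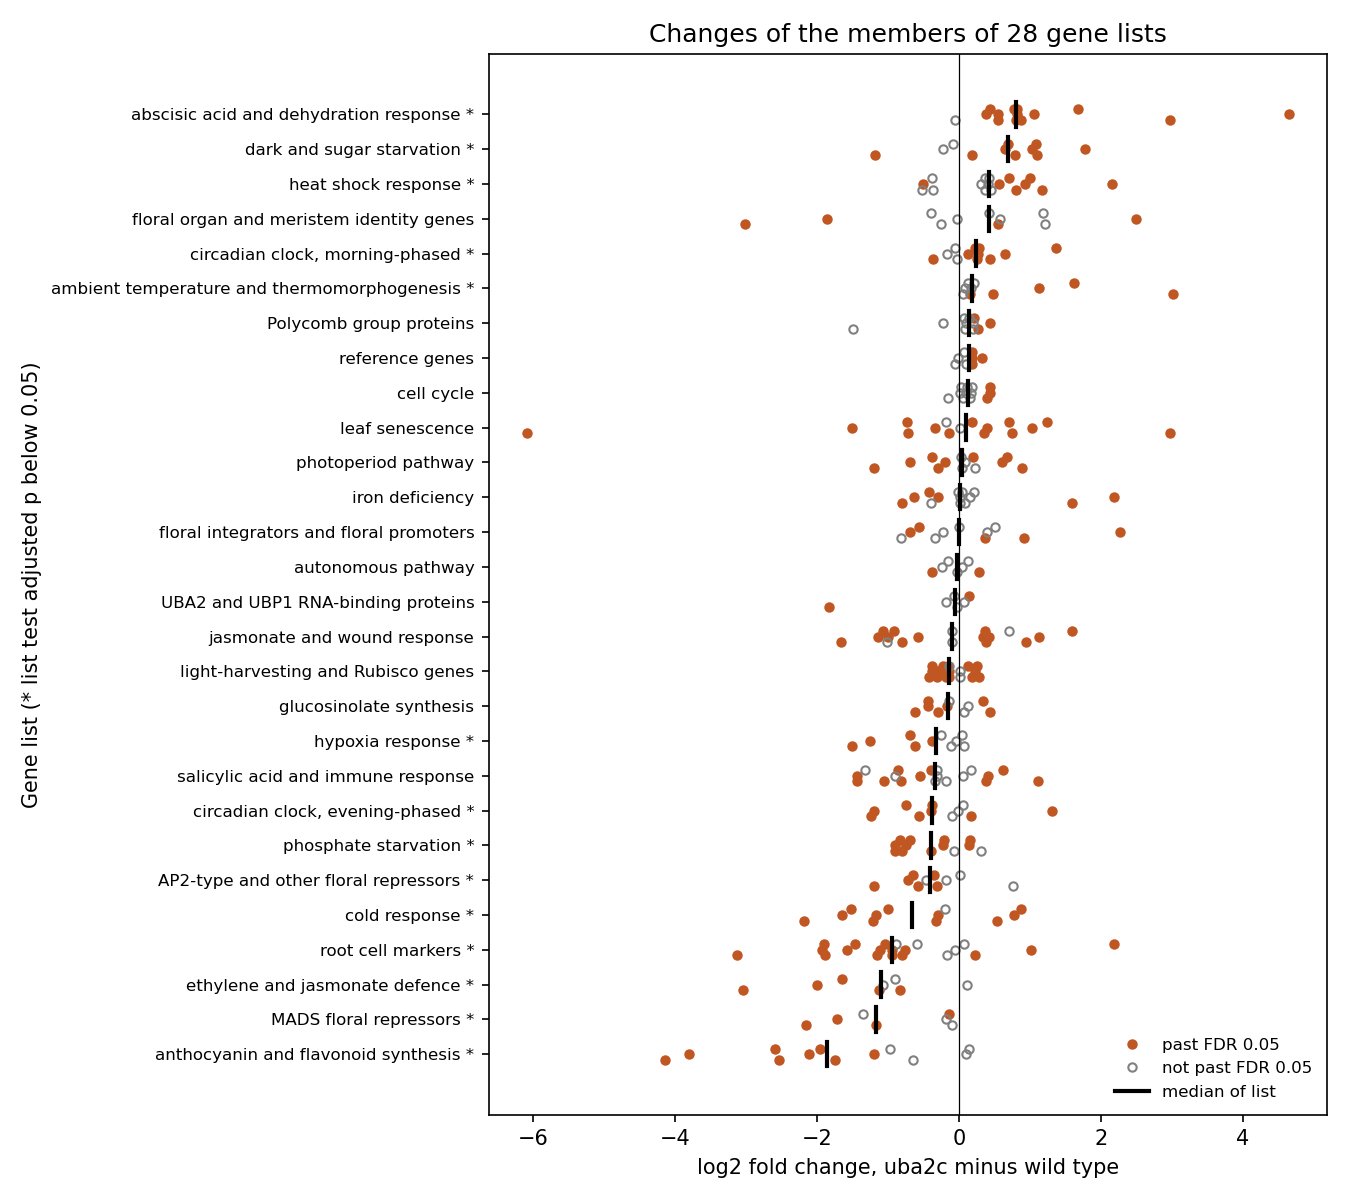
Log2 fold change (uba2c minus wild type) of each tested member of the 28 lists, with filled points past an FDR of 0.05 in limma, open points not past it and a black bar at each list's median. The abscisic acid list has the highest median (0.81) and the anthocyanin list the lowest (−1.85).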

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

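The edgeR quasi-likelihood test, edgeR without each library and the GC and length correction were chosen after seeing the data. The UBA2C transcript and FLM transcript stayed lower in every alternative, from −1.91 to −1.75 and from −1.75 to −1.62. With limma, leaving out each library in turn gave −1.91 to −1.75 for the UBA2C transcript and −1.75 to −1.68 for the FLM transcript, and both lost their call without uba2c 1 (adjusted p = 0.0837) or uba2c 2 (0.0828). In the same fits the number of genes past the FDR ranged from 0 to 6519, with 0 to 3352 higher and 0 to 3167 lower. limma's prior degrees of freedom fell from 5.90 to 1.13 without either uba2c library, where 7513 and 7412 genes had an unadjusted p under 0.05, and edgeR called 5828 and 6492. DESeq2 called 4804 genes (2454 higher, 2350 lower); the cause was not tested. A log2 change of at least 1 left 1372 (513 and 859) and an FDR of 0.01 left 4526 (2268 and 2258), by construction. The other alternatives called 6412 (no filter) to 9324 genes (edgeR likelihood ratio test), and 8440 after the GC and length correction, where 4815 were higher and 3625 lower (57.0% higher, against 50.0%). With edgeR on library totals the split was 4137 higher and 4612 lower (47.3% higher). With an estimated correlation 0 lists passed, and with fry, which tests whether a list moves on balance and not against other genes, 23 passed. Lists also gained calls: jasmonate and wound in 11 of 22 alternatives, leaf senescence in 10, light-harvesting in 5, salicylic acid in 4, Polycomb in 2, and cell cycle, glucosinolate, iron deficiency, reference genes and UBA2 and UBP1 in 1 each (fry). The morning and cold lists lost theirs in 11 each and the evening list in 3. Of 2367 values of the 124 named genes under alternatives, 2096 kept their side of the threshold, 263 lost the call and 8 gained it (MAF2). With a call in either fit, 0 reversed direction. Where neither fit made a call, as for TSF, a change of direction was not counted.

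With the replicate number as a block, 8025 genes passed. Deviations of same-numbered libraries correlated at r = 0.0173 across 16851 genes, which are not independent replicates, and the labels do not tie the numbers to a batch, so the numbers are not taken to pair the libraries. The alternative with nuclear genes only was not run, since no chloroplast or mitochondrial gene is among those analysed here. At 19720586 to 19847651 reads per library, genes with few reads, such as FLC, TSF and CO, allow no firm statement.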

Other observations

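The tests of replicate spread, root markers, clock phase and the telo-box were chosen only after the result, or part of it, was seen, as were the shade genes, the symbol families and the GC and length correction as an alternative. Of the 7 root hair genes, at least PRP3, EXPA7, LRX1 and RSL4 had been seen to fall before that test was set. Genes known from shade and auxin responses, 15 of them picked after their values were seen, were higher in 12 cases and lower in 0 (median log2 fold change 1.12). PIL1 rose from 37.3 to 413 (log2 fold change 3.45, limma adjusted p = 9.35e-07), HFR1 from 271 to 2696 (3.32), HB4 from 18.9 to 132 (2.78) and YUC9 from 51.9 to 307 (2.59), while IAA6, PAR2 and BEE1 did not pass. Since the genes were picked for their values, the count is a description and no test.

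Of 142 families of genes with a shared symbol, 12 passed in camera at the preset correlation and 0 with an estimated one. Arabinogalactan protein genes (AGP) fell in 14 and rose in 2 of 28 cases, and beta-glucosidase genes (BGLU) fell in 14 and rose in 3 of 30 (camera adjusted p = 0.00140 for both, adjusted p = 0.869 with an estimated correlation). WRKY genes fell in 24 and rose in 6 of 60, and small ribosomal subunit genes (RPS) rose in 11 and fell in 0 of 22 (camera adjusted p = 0.0490 for both, adjusted p = 0.869 with an estimated correlation). The families ERD, HSP, EIF, IAA and TOC (higher) and MYB, PUP and FLA (lower) were at the same adjusted p of 0.0490. Large ribosomal subunit genes (RPL), with 6 of 20 up and 1 down, did not pass (camera adjusted p = 0.293).

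Of the tested genes 34.8% passed the FDR. A bias of GC content or gene length between the libraries is argued against as the whole cause, since 90.9% of the genes that passed still did so in the same direction after a smooth trend of both was removed. That correction moved the balance of calls from 50.0% to 57.0% higher, and edgeR on library totals gave 47.3% higher, so the split of directions depends on the correction and on the scaling. Replicates that share plants or RNA remain open: the larger of the replicate pairs' median squared deviations was 1.52 times sampling noise, and the labels do not say whether plants were separate. The spread between cultures could then be larger than that measured, and an effect of the genotype stays open beside it.

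Root cell markers were lower in uba2c. Less root tissue as the whole cause would lower them alike, but the 21 markers of the list ranged from −3.13 to 2.18 on the log2 scale, 13 fell and 3 rose, and their squared spread was 177 times that of measurement error (Cochran's Q over 20 degrees of freedom, with limma's standard errors). This comparison was set after the values were seen, and the standard errors come from replicates that may be technical. The values show that the markers did not fall alike, but give no test of the cause. A smaller share of root tissue as part of the cause is not excluded, and IRT1 and NRT2.1, which rose, also respond to nutrients. The same limit covers any gene of the other lists that is transcribed mainly in roots. Which genes are so was not tested. The root hair markers had a median of −1.89 and the other root markers one of −0.68, a difference of −1.21. Since that division of the list was made after several of its genes had been seen to fall, it tests nothing, and a change among root hair cells stays open.

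Morning-phased clock genes were higher and evening-phased ones lower, with medians of 0.24 and −0.38 on the log2 scale, a difference of 0.62. This describes lists already seen to move apart and adds no test: both lists lost their call with an estimated correlation (adjusted p = 0.295 each) and in limma without uba2c 1 (0.0970 and 0.137) or uba2c 2 (0.0749 and 0.0533). Harvest at another time of day and an effect of the genotype on the clock cannot be told apart, since the labels give no time of harvest. The same limit covers any other gene given above whose transcript varies over the day, in the flowering, cold, sugar starvation and other lists. Which of those genes vary so was not tested.

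Sequence motifs were counted in the 1000 bp upstream of 3838 protein-coding genes that rose and 3830 that fell, as hypotheses, with Fisher's exact test (two-sided, adjusted over 5 motifs) and 100 shuffled versions of each motif. The G-box CACGTG was more frequent upstream of genes that rose (odds ratio 1.28, adjusted p = 7.14e-05, above 98% of its shuffled versions), as was the abscisic acid response element (1.37, adjusted p = 2.85e-06, above 98%). The evening element AAATATCT was less frequent there (0.76, adjusted p = 2.71e-05, below all 100). The G-box and the abscisic acid response element share the bases ACGTG, so the same site can match both. Genes holding either of them without the other were not counted, so their shifts are not shown to be separate. The CArG box, bound by MADS-domain proteins such as FLM, showed no detectable difference (odds ratio 1.03, adjusted p = 0.751). The telo-box had an odds ratio of 1.37 (adjusted p = 5.83e-05, above 99%), but its prediction was written after this value was seen, so it stands as a value only. These are small shifts in frequency, and genes are not independent replicates.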
